A study of Homo sapiens with 12 samples.

How the data were processed

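Gene expression was measured by sequencing poly(A) RNA of 12 libraries of OCI-Ly7 cells, 3 in each of 4 groups that the sample titles name: vehicle, HDAC3 inhibitor, 5-azacitidine and both drugs. Per the labels, RNA was isolated with Trizol and a column kit, messenger RNA was reverse transcribed with random primers, and the libraries were made as single-stranded circles after amplification by PCR. Per the submitters' processing notes, reads were handled with bcl2fastq 2.17.1.14, FastQC 12.1, cutadapt 5.1, STAR 2.7.11b and Subread 2.1.2 on GRCh38. The values are the expected counts per gene that the authors deposited: per the file headers, featureCounts 2.1.1 counted reads over the exons of each of 78892 genes of the release 114 annotation, splitting reads that map to several places into fractions, without regard to strand and leaving out reads that overlap more than 1 gene. The header gives paired-end input without the option that counts read pairs, so whether a count is a read or a pair was not settled, and it names Subread as 2.1.1 where the notes say 2.1.2. Of the values, 96.9% were whole within 1e-06, and 10.1% of the genes had a fractional value in some library. The header lists 16 libraries, 4 of which were not analysed here. Library totals ranged from 35.948 to 36.337 in units of 1e+06 counts, and a gene with 0 counts in a library was given an upper limit of 3 counts, 0.0826 to 0.0835 CPM, where CPM is counts scaled to 1e+06 per library.

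Counts were rounded to whole numbers and analysed in R 4.3.3. Genes were kept by the filterByExpr function of edgeR 4.0.16 on the 4 groups, which left 17869 genes with 99.93% of the counts, and libraries were scaled with TMM factors. All 12 libraries were fitted together with 1 mean per group and no other term, and each comparison was tested with the edgeR quasi-likelihood F-test, two-sided, with Benjamini-Hochberg adjustment over all genes of the comparison. A gene was called at an adjusted p under 0.05. The 6 comparisons were each drug and the combination against vehicle, the combination against each drug, and the interaction, that is the 5-azacitidine effect on the inhibitor minus that without it. Log2 CPM values, as in the principal components and GC slopes, used a prior count of 2, and log2 fold changes the default prior count of edgeR. The biological coefficient of variation was 6.05%, and the largest median log2 change of all genes over the comparisons of 2 groups was 0.0139.

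The comparisons, tests, alternatives, gene lists and the rule for named genes were set before the data were examined. The rule takes, among called genes with a symbol, protein-coding where the biotype is known (GENCODE 29) a mean of at least 5 CPM in the highest group compared and, between 2 groups, no overlap of their libraries, the 8 largest rises and 8 largest falls in each comparison with vehicle, 5 and 5 in each comparison with a single drug and 4 and 4 in the interaction. It adds 10 regulators in every comparison, and the 4 members of smallest adjusted p in each list, from which examples were taken. Of 44 lists, 42 had at least 5 tested members and were tested with camera of limma 3.58.1, two-sided, on voom values with a preset correlation between genes of 0.01, adjusted by Benjamini-Hochberg over the lists of a comparison, and again with an estimated correlation; fry was run as an alternative. Genes beyond both single drugs were counted from the 2 comparisons with a single drug, beside 10 simulations of unchanged groups. Correlations of effects across genes have a jackknife SE over libraries, with the genes filtered anew in each fit.

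The alternatives tried were DESeq2 size factors, library totals only, no filter on low counts, a stricter filter of 5 CPM in at least 3 libraries, DESeq2 1.42.0 and limma voom in place of edgeR, only the 2 groups compared, the replicate number of the titles or the number in the library names as a block, a fold threshold, and leaving out each library. Alternatives added after seeing the data were an offset per gene and library for GC content and exonic length, leaving out the 2 libraries of highest mitochondrial share, and leaving out mitochondrially encoded genes. The table was prepared and the figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

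The fits were tested on simulated data with 50 changed genes per fold among 17869. The share of changed genes that edgeR recovered at 1.25-fold, 1.5-fold, 2-fold and 4-fold was 44%, 56%, 76% and 94% for the inhibitor against vehicle, with 13 false calls of 148. The shares were 42%, 62%, 74% and 90% for 5-azacitidine against vehicle (10 false of 144) and 40%, 60%, 78% and 96% for the combination against vehicle (5 false of 142). For the combination against 5-azacitidine they were 32%, 52%, 76% and 92% (9 false of 135), and against the inhibitor 30%, 58%, 76% and 98% (8 false of 139). For the interaction they were 14%, 46%, 70% and 84% (4 false of 111), so changes under 2-fold were often missed there. On simulated data with a GC trend, the corrected fit recovered 50 of 50 changed genes with 4 false calls, against 1123 false calls without the correction, and camera called the raised list and none of 40 unchanged lists. The simulated genes were independent, so this could not show false list calls from correlated genes. In the data the G2 and M phase genes, for example, had an estimated correlation of 0.13.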

Results

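Messenger RNA was sequenced from OCI-Ly7 cells, a human line of diffuse large B-cell lymphoma of germinal-centre type. The cells received an HDAC3 inhibitor, 5-azacitidine, both drugs or vehicle. HDAC3 is a histone deacetylase that works in co-repressor complexes, and 5-azacitidine is a cytidine analogue that is built into RNA and DNA and traps DNA methyltransferases. 5-azacitidine was given at 100 nM every day from day 0 to day 4, the inhibitor at 15 µM on days 2 and 4, and the cells were harvested on day 5. The compound used as the inhibitor is not named in the sources used here. There were 4 groups of 3 libraries: vehicle, inhibitor, 5-azacitidine and the combination. The series title gives the purpose as the efficacy of the inhibitor together with 5-azacitidine against this lymphoma. The 12 libraries held between 35947872 and 36337086 counts each. The mean number of genes with a count was 24563 ± 259 (SD, n = 3) in vehicle, 26750 ± 162 with the inhibitor, 24997 ± 207 with 5-azacitidine and 27142 ± 229 with the combination. The labels do not say whether the 3 libraries of a group came from separate cultures, so every p-value measures only the spread between these libraries, which may be technical.

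The first principal component held 69.6% of the variance between libraries and separated the libraries with the inhibitor from those without it. The second held 5.16% and separated the libraries with 5-azacitidine from those without it. Mitochondrially encoded genes took 10.03% ± 0.480 (SD, n = 3) of the counts in vehicle, 12.5% ± 0.452 with the inhibitor, 11.3% ± 2.12 with 5-azacitidine and 13.6% ± 1.51 with the combination. The highest shares within their groups were 13.8% in 5-azacitidine replicate 1 and 15.3% in combination replicate 3. 5-azacitidine replicate 1 also stood apart in its counts, with a chi-square per degree of freedom of 33.0 and 29.6 against replicates 2 and 3, which differed from each other by 4.55. The pairs of combination libraries differed by 11.4, 15.4 and 18.8. Pairs of vehicle libraries and pairs of inhibitor libraries differed by 3.81 to 7.78.

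**Figure D1:**
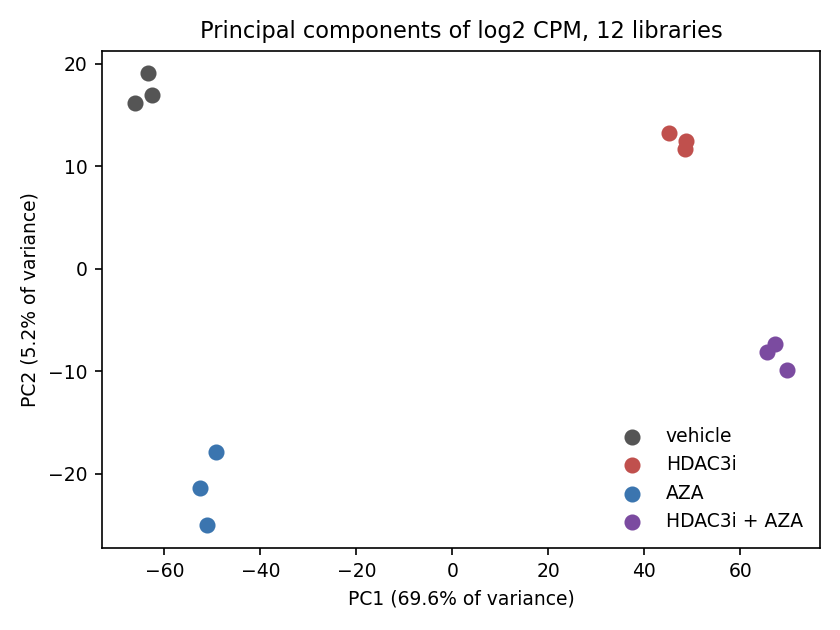
Principal components of log2 CPM (read counts scaled to a common library size) for the 12 libraries, coloured by group, with component 1 (69.6% of the variance) on the horizontal axis and component 2 (5.16%) on the vertical axis, both in arbitrary units. The 6 libraries with the inhibitor lie to the right of the 6 without it, and the 6 libraries with 5-azacitidine lie below the 6 without it.

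The comparison of the inhibitor with vehicle asks which genes the inhibitor changed by itself. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose 34.0-fold, from 0.996 ± 0.199 CPM to 33.9 ± 3.07 CPM (SD, n = 3; log2 fold change 5.08 ± 0.12 SE, adjusted p = 7e-22). PRAME, a germline gene that many tumours express, had no counts in any vehicle library, which allows up to 0.0828 to 0.0832 CPM (a floor of 3 counts per library), and 8.36 ± 1.20 CPM with the inhibitor. PRDM1, the repressor that drives plasma-cell differentiation, rose 4.08-fold to 9.29 ± 0.583 CPM. TERT, the catalytic subunit of telomerase, fell from 114 ± 4.28 to 51.5 ± 0.841 CPM (log2 fold change −1.15 ± 0.07 SE, adjusted p = 1.46e-13). CDKN1A (ENSG00000124762) lies on chromosome 6 of GRCh38 at 36676460 to 36687397, PRAME (ENSG00000185686) on chromosome 22 at 22547701 to 22559361 and TERT on chromosome 5 at 1253147 to 1295068. Floors for genes without counts cover counting error only, since reads amplified by PCR without molecular identifiers are not independent molecules.

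The other genes of largest rise were BANK1, a B-cell adaptor with 4 counts over the vehicle group (log2 fold change 7.12 ± 0.41 SE), ALDH1A1, a retinal dehydrogenase (6.72 ± 0.27), the receptor tyrosine kinase gene ERBB3 (5.45 ± 0.24), MOXD1 (5.41 ± 0.19), the integrin gene ITGAM (5.08 ± 0.20) and ARHGAP24 (4.93 ± 0.26). All 6 were under 0.5 CPM in vehicle. Larger falls than that of TERT were found for DBH, SARDH, PRKAR2B, KLF15, FBP1 and RAB40B, from −1.20 for RAB40B to −1.99 ± 0.18 for DBH (6.08 to 1.53 CPM, adjusted p = 3.75e-10). SVIL-AS1 also read −1.53, but the counting ignored strand, so its reads cannot be separated from those of the gene on the other strand. Among the chosen regulators, the DNA methyltransferase genes DNMT3A (0.73 ± 0.10) and DNMT3B (0.61 ± 0.09) rose, as did MYC (0.32 ± 0.06) and the class II transactivator CIITA (0.33 ± 0.07). UHRF1, which guides DNMT1 to replicating DNA, fell by 0.39 on the log2 scale (adjusted p = 1.11e-07). The transcript of the inhibitor's target, HDAC3, did not pass the test (0.02 ± 0.05, adjusted p = 0.731), nor did DNMT1 (0.03, adjusted p = 0.66). BCL6, a transcriptional repressor of germinal-centre B cells, fell by 0.18 (adjusted p = 0.00501), a call that ended with a stricter filter on low counts (−0.10, adjusted p = 0.0746).

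Genes of antigen presentation and interferon response rose as lists. The call of every list in the text held with an estimated correlation between genes unless the adjusted p with that correlation is given. Of 46 measured interferon-stimulated genes 31 rose and 5 fell, with a median log2 change of 0.78 (camera adjusted p = 2.52e-07), among them OAS3 at 1.76, PARP9 at 3.55 and DTX3L at 2.33. Of 18 genes of MHC class II presentation 14 rose and 2 fell (median 0.79, adjusted p = 1.35e-06), with HLA-DRA at 1.07 and HLA-DMA at 0.97. Reads of HLA genes can be shared between paralogs, which makes single members uncertain. Of 24 genes of costimulation and immune checkpoints 17 rose and 2 fell (median 0.76, adjusted p = 8.19e-05), such as TNFSF9 at 1.45 and VSIR at 1.37. Of 26 genes that BCL6 represses 17 rose and 8 fell (median 0.76, adjusted p = 0.000182). Members of that list that rose were FCER2, the low-affinity IgE receptor of mature B cells, at 2.92, the complement receptor CR2 at 1.34 and CD86 at 1.21. Of 17 plasma-cell genes 12 rose and 3 fell (median 0.45, adjusted p = 0.000294), XBP1 by 2.12. Of 26 NF-kB targets and inflammatory genes 15 rose and 6 fell (median 0.57, adjusted p = 0.00363), TNF by 2.34 and CD83 by 1.26. Counts adjusted over the list alone were 18 and 2 for costimulation and 16 and 6 for NF-kB, and were the same as those over all genes for the other lists of this paragraph. MHC class I presentation (11 rose and 5 fell of 20, adjusted p = 0.00212) and B-cell receptor signalling (17 rose and 5 fell of 29, adjusted p = 0.000363) lost their calls (adjusted p = 0.0999 and adjusted p = 0.0669 with an estimated correlation).

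Genes of growth and division fell. Genes of at least 5 CPM in general fell more often than they rose, in each bin of genomic span up to 400 kb. Bin medians ran from −0.13 (25 to 50 kb, 1015 lower and 446 higher of 2251) to 0.07 (over 400 kb, 31 and 49 of 129). Camera compared lists with all tested genes, low ones included. With the stricter filter, 102 list results over all comparisons kept their call and 7 lost it. CPM, scaled per library, do not show whether RNA per cell changed. Of 56 genes of the G2 and M phases 46 fell and 3 rose (median −0.37, adjusted p = 4.37e-12), including PLK1 at −0.55 and CCNB1 at −0.52. Of 40 MYC and ribosome biogenesis genes 31 fell and 1 rose (median −0.38, adjusted p = 1.25e-11), with TSR1 at −0.69 and WDR12 at −0.58. Of 48 S-phase genes 33 fell and 2 rose, or 34 and 2 adjusted over the list alone (median −0.21, adjusted p = 1.41e-07), such as CCNE1 at −0.81 and UNG at −0.69; the list had an adjusted p = 0.057 with an estimated correlation. Of 27 histone acetyltransferases and methyltransferases 22 fell and none rose, or 24 adjusted over the list alone (median −0.30, adjusted p = 3.51e-06), among them CREBBP at −0.61 and KAT2A at −0.57. Nuclear-encoded genes of oxidative phosphorylation fell in 16 of 33 and rose in none (adjusted p = 0.000182; adjusted p = 0.21 with an estimated correlation). The mitochondrially encoded messenger RNAs, whose share was higher with the inhibitor, rose in 4 of 13, or 3 adjusted over the list alone (adjusted p = 0.0486; adjusted p = 0.56 with an estimated correlation). This call was lost in fry (adjusted p = 0.164), without vehicle replicate 1 (0.128) or 2 (0.0677) without any inhibitor replicate (0.0596 to 0.0707) and with the GC and length correction (0.279).

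Genes of other cell types rose as well. Of 16 genes of T and NK cells 14 rose and 2 fell (adjusted p = 8.19e-05), and of 13 genes of monocytes and granulocytes 9 rose and 1 fell (median 1.26, adjusted p = 0.00363). CCR7 rose by 4.28, IL7R by 1.57 and CLEC7A by 4.90. The most abundant granulocyte transcripts S100A8 and S100A9 were at 0 CPM in the inhibitor group. Of 10 measured cancer-testis and germline genes 7 rose and none fell (adjusted p = 0.0232; adjusted p = 0.154 with an estimated correlation). That preset call ended without vehicle replicate 1 (adjusted p = 0.0687), vehicle replicate 3 (0.0507), inhibitor replicate 2 (0.0537) or 5-azacitidine replicate 1 (0.0514). The 10 were of 84 such genes in the table. Tested were 16 of 28 T and NK cell genes and 13 of 25 of monocytes and granulocytes. The filter on low counts used all groups, so members silent in vehicle were tested mainly where a drug raised them. Rises in these lists were therefore partly fixed by the filter. Lists that did not pass the test were apoptosis regulators (12 rose and 11 fell of 31, adjusted p = 0.653), with BMF at 2.55 and BID at −0.67, p53 targets (13 rose and 6 fell of 25, adjusted p = 0.118), germinal-centre B-cell genes (8 rose and 9 fell of 28, adjusted p = 0.876) and annotated endogenous retroviral genes (none rose and 4 fell of 5, adjusted p = 0.11).

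In all, 4712 genes rose and 4454 fell of 17869 tested, 51.3%, at an adjusted p under 0.05. At least 2-fold changes were far from even, with 2240 genes higher and 155 lower. The stricter filter of 5 CPM in at least 3 libraries, which tests fewer genes, gave 3019 higher and 3117 lower. Of the lists tested, 19 rose and 8 fell with the preset correlation between genes, and 9 and 3 with an estimated one. The rule for the genes of largest change required that the libraries of the compared groups did not overlap, which chance gives for 10% of genes with 3 libraries against 3, and the called regulators did not overlap either.

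The comparison of 5-azacitidine with vehicle asks what 5-azacitidine changed by itself, and the changes were smaller. FGR, a SRC-family kinase of myeloid and B cells, rose 3.22-fold from 2.57 ± 0.557 to 8.28 ± 0.456 CPM (SD, n = 3; log2 fold change 1.68 ± 0.11 SE, adjusted p = 1.18e-10). CDKN1A rose 2.97-fold to 2.96 ± 0.415 CPM (adjusted p = 4.46e-07). FCER2 rose from a mean of 11.9 to 23.7 CPM (0.99 ± 0.07 SE, adjusted p = 2.61e-10), and BMF, a pro-apoptotic member of the BCL2 family, rose 2.35-fold. RPTOR, the subunit that defines mTOR complex 1, fell from 95.6 ± 3.43 to 50.3 ± 2.49 CPM (−0.93 ± 0.06, adjusted p = 3.57e-11).

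The other genes of largest rise were MPEG1, which encodes a pore-forming protein of phagocytes (1.26 ± 0.06), DBNDD1 (1.13 ± 0.13), TNNT1 (1.08 ± 0.09), MYBPC2 (1.03 ± 0.07) and LRRC25 (2.01-fold). The other genes of largest fall were CAMK1D (−0.94 ± 0.07), KLF15 (−0.81 ± 0.17), TRAPPC9 (−0.80 ± 0.08), STX8 (−0.78 ± 0.08), RASL10A (−0.74 ± 0.13) and ADAT3 (−0.70 ± 0.14). Among the chosen regulators UHRF1 fell by 0.30 (adjusted p = 9.78e-05) and MYC by 0.24 (adjusted p = 0.00607), the latter call ending without vehicle replicate 1 (adjusted p = 0.0563). DNMT1, which 5-azacitidine traps as a protein, had a transcript change of −0.16 ± 0.05 that missed the test (adjusted p = 0.0551) and passed it in 9 alternative fits (adjusted p from 0.0053 to 0.0499). No change was called for HDAC3 (−0.05, adjusted p = 0.662), DNMT3A (0.06, adjusted p = 0.795), DNMT3B (0.05, adjusted p = 0.807), CIITA (−0.15, adjusted p = 0.198), BCL6 (−0.12, adjusted p = 0.181) or PRDM1 (0.07, adjusted p = 0.846).

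Interferon-stimulated genes rose in 12 of 46 and fell in none, or 15 adjusted over the list alone, with a median of 0.23, or 0.20 with genes at 0 in a group set to their bound (adjusted p = 1.9e-06). PARP9 rose by 1.37, IRF7 by 0.51 and OAS3 by 0.50. Of 26 BCL6-repressed genes 7 rose and 1 fell, or 10 and 1 adjusted over the list alone (median 0.15, or 0.07 at the bound, adjusted p = 0.000133), with CXCR5 at 0.94 and CD86 at 0.59. MHC class II presentation rose in 6 of 18, or 9 adjusted over the list alone (median 0.18, adjusted p = 2.92e-05; adjusted p = 0.0736 with an estimated correlation), HLA-DRA by 0.22. Costimulation genes rose in 6 of 24, or 8 adjusted over the list alone (adjusted p = 0.000175; adjusted p = 0.0555 with an estimated correlation). NF-kB targets rose in 7 of 26, or 8 adjusted over the list alone (adjusted p = 0.00794; adjusted p = 0.0736 with an estimated correlation), with BIRC3 at 0.43 and CD83 at 0.35.

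ATF4 targets of the integrated stress response fell in 9 of 24 and rose in none, or 11 and 1 adjusted over the list alone (median −0.19, adjusted p = 8.31e-06; adjusted p = 0.0944 with an estimated correlation), with ATF5 at −0.53 and PHGDH, the entry enzyme of serine synthesis, at −0.43. Glycolysis and hypoxia genes fell in 7 of 27 and rose in 1, or 10 and 1 adjusted over the list alone (median −0.14, or −0.13 at the bound, adjusted p = 1.25e-05; adjusted p = 0.202 with an estimated correlation), with PFKP at −0.37 and HK2 at −0.31. MYC and ribosome biogenesis genes fell in 10 of 40 (adjusted p = 2.92e-05; adjusted p = 0.248 with an estimated correlation). T and NK cell genes, with 2 higher and 1 lower of 16 or 5 and 1 adjusted over the list alone, were called higher (adjusted p = 0.0256; adjusted p = 0.202 with an estimated correlation). That call was lost without vehicle replicate 1 (adjusted p = 0.0677), 5-azacitidine replicate 1 (0.0594) or the pair of libraries of highest mitochondrial share (0.059). Heat shock genes, with 2 higher of 17, were called higher (adjusted p = 0.0256; adjusted p = 0.442 with an estimated correlation). That call was lost in fry (0.206), without vehicle replicate 2 (0.112) or 3 (0.0802), 5-azacitidine replicate 1 (0.176) or 2 (0.0608), or the pair (0.155). Lists of genes that DNA methylation is known to silence were not called. None of 10 cancer-testis genes (adjusted p = 0.616) and none of 15 imprinted genes (adjusted p = 0.905) was called, 1 rose and 1 fell of 5 endogenous retroviral genes (adjusted p = 0.878), and 3 rose and 1 fell of 15 hypermethylated tumour suppressors (adjusted p = 0.337). The tested genes were of 84, 32, 24 and 32 in these lists, in the same order. The others had too few counts to pass the filter, so these results cover only part of each list. S-phase genes (2 rose and 3 fell of 48, adjusted p = 0.754) and G2 and M phase genes (4 rose and 1 fell of 56, adjusted p = 0.0646) were not called either.

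In all, 770 genes rose and 849 fell, 9.06% of those tested, with 152 higher and 13 lower by at least 2-fold. These counts depended on single libraries: 497 rose and 520 fell without vehicle replicate 1, 538 fell without vehicle replicate 3 and 508 fell without 5-azacitidine replicate 2. Without the pair of libraries of highest mitochondrial share, one of which is 5-azacitidine replicate 1, 733 rose and 853 fell, and 76.2% and 80.6% of the calls were kept.

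The comparison of the combination with vehicle asks what both drugs changed together. CDKN1A rose 63.8-fold to 63.6 ± 2.65 CPM (SD, n = 3; log2 fold change 5.99 ± 0.12 SE, adjusted p = 8.06e-24). PRAME was at least 140-fold higher than the floor at 11.7 ± 1.55 CPM, and EBI3, a cytokine subunit, at least 85.8-fold higher at 7.13 ± 0.124 CPM, with no vehicle counts for either. TERT fell to 39.2 ± 5.41 CPM (−1.54 ± 0.07, adjusted p = 2.69e-16), and MYBL1, a transcription factor of germinal-centre B cells, fell from 64.9 ± 1.79 to 25.7 ± 3.04 CPM (−1.34 ± 0.07, adjusted p = 3.55e-15). The other genes of largest rise, all under 0.2 CPM in vehicle, were CAVIN1 (7.30 ± 0.35, with 4 vehicle counts), ALDH1A1 (7.09 ± 0.26), COL1A1 (6.76 ± 0.37, with 6 vehicle counts), the chemokine receptor CX3CR1 (6.53 ± 0.33), ERBB3 (6.10 ± 0.22) and CCM2L (66.4-fold). The other genes of largest fall were DBH (−1.67), KLF15 (−1.53), SARDH (−1.54), PRKAR2B (−1.47), SVIL-AS1 (−1.43, uncertain as above) and ZDHHC11 (−1.36).

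Of the chosen regulators, PRDM1 (1.95, adjusted p = 1.75e-13), DNMT3B (0.84, adjusted p = 2.67e-09), DNMT3A (0.75, adjusted p = 1.78e-07), CIITA (0.31, adjusted p = 0.000333) and MYC (0.31, adjusted p = 3.35e-05) rose, and UHRF1 fell by 0.61 (adjusted p = 1.52e-11). HDAC3 (0.07, adjusted p = 0.278), DNMT1 (−0.03, adjusted p = 0.681) and BCL6 (−0.09, adjusted p = 0.132) were not called, although BCL6 was called with a correction for GC content and length (−0.20, adjusted p = 0.000165).

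Of 46 interferon-stimulated genes 37 rose and 3 fell, or 37 and 4 adjusted over the list alone (median 0.88, adjusted p = 2.21e-09), with PARP9 at 4.00 and OAS3 and IFI6 at 2.12. Of 18 MHC class II genes 16 rose and 2 fell (median 0.97, adjusted p = 3.19e-07). Costimulation genes rose in 17 of 24 and fell in 1, or 18 and 1 adjusted over the list alone (adjusted p = 1.06e-05), with TNFSF9 at 1.80. BCL6-repressed genes rose in 18 of 26 and fell in 7, or 18 and 8 adjusted over the list alone (adjusted p = 0.000197), with FCER2 at 3.28. NF-kB targets rose in 17 of 26 and fell in 4 (adjusted p = 0.000509), with CD83 at 1.88. Of 31 genes of cholesterol synthesis and uptake 22 rose and 2 fell (median 0.30, adjusted p = 0.000124), with MSMO1 at 0.88 and HMGCS1 at 0.60 against FASN at −0.61. S-phase genes fell in 42 of 48 and rose in none (median −0.42, adjusted p = 7.14e-12), with UNG at −0.84 and WDR76 at −0.64. MYC and ribosome biogenesis genes fell in 34 of 40 and rose in 1, or 35 and 1 adjusted over the list alone (median −0.49, adjusted p = 1.98e-12). DNA damage response genes fell in 20 of 30 and rose in 1, or 20 and 2 adjusted over the list alone (median −0.32, adjusted p = 3.21e-05), with XRCC2 at −0.70 and BRCA2 at −0.65. G2 and M phase genes fell in 43 of 56 and rose in 3, or 44 and 3 adjusted over the list alone (median −0.33, adjusted p = 2.11e-09; adjusted p = 0.0612 with an estimated correlation). Mitochondrially encoded messenger RNAs rose in 9 of 13, or 13 adjusted over the list alone (median 0.41, adjusted p = 0.00926; adjusted p = 0.423 with an estimated correlation, and 0.0562 with the GC correction). The 17 heat shock genes, with 4 higher and 9 lower, were called lower (adjusted p = 0.0378; adjusted p = 0.408 with an estimated correlation). Their median of −0.27 and mean of 0.08 differ in sign, and the call ended without vehicle replicate 1 (adjusted p = 0.0719), combination replicate 3 (0.0696) or the pair of libraries of highest mitochondrial share (0.0634), and with the stricter filter (0.209). In all, 5298 genes rose and 4909 fell, 57.12% of those tested, with 2658 higher and 228 lower by at least 2-fold. With the stricter filter 3378 were higher and 3564 lower.

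**Figure D2:**
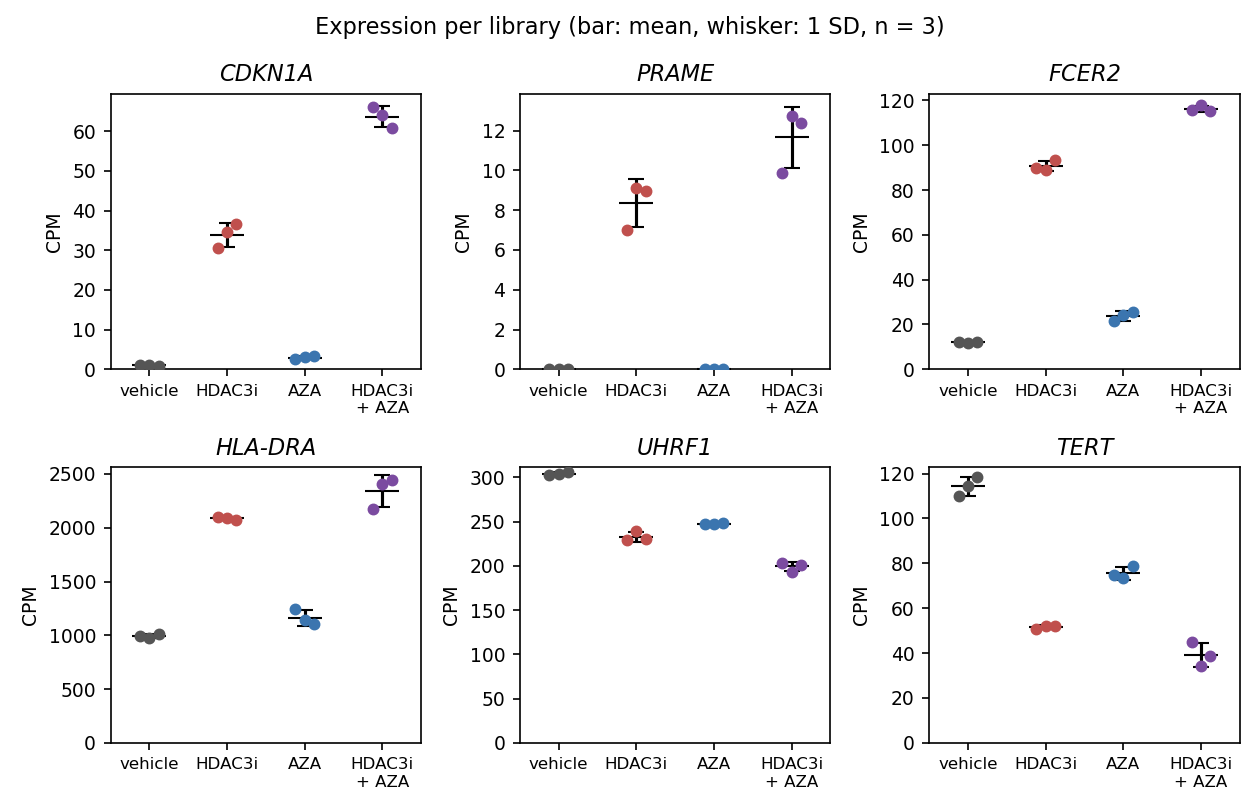
Expression of 6 genes in CPM (linear vertical axes from 0) in each library of the 4 groups, where points are libraries, long bars are means and whiskers are 1 SD (n = 3). CDKN1A reached 63.6 CPM in the combination against 33.9 with the inhibitor and 2.96 with 5-azacitidine, and PRAME was at 0 in every library without the inhibitor.

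The comparison of the combination with 5-azacitidine asks what the inhibitor added to cells that already had 5-azacitidine. CDKN1A rose 21.5-fold (log2 fold change 4.42 ± 0.10 SE, n = 3, adjusted p = 4.15e-22), PRAME was at least 141-fold higher, and ALDH1A1 (7.48 ± 0.27), CCM2L (6.56 ± 0.36), ERBB3 (6.40 ± 0.23) and EBI3 (6.22 ± 0.29) had the next largest rises. The largest falls were those of DBH (−1.60), SARDH (−1.46), SVIL-AS1 (−1.44), MYBL1 (−1.36) and HELQ, a helicase of DNA repair (−1.21 ± 0.05, from 133 ± 5.07 to 57.4 ± 2.66 CPM). PRDM1 (1.89, adjusted p = 4.21e-13), DNMT3B (0.79, adjusted p = 9.67e-09), DNMT3A (0.69, adjusted p = 7.46e-07), MYC (0.56, adjusted p = 4.74e-09) and CIITA (0.46, adjusted p = 2.47e-06) rose and UHRF1 fell by 0.31 (adjusted p = 2.45e-06). HDAC3 (0.11, adjusted p = 0.0635) and BCL6 (0.02, adjusted p = 0.733) were not called. DNMT1 passed at 0.13 ± 0.05 (adjusted p = 0.0357), with libraries that overlapped, and lost its call in 9 alternative fits, one of which turned its sign (−0.005 with the GC correction).

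S-phase genes fell in 42 of 48 and rose in none, or 44 and 1 adjusted over the list alone (median −0.35, adjusted p = 2.46e-13), and G2 and M phase genes fell in 48 of 56 and rose in 3 (median −0.35, adjusted p = 2.08e-12), with SMC4 at −0.79 and NUF2 at −0.84. DNA damage response genes fell in 19 of 30 and rose in 2, or 21 and 2 adjusted over the list alone (adjusted p = 3.61e-05), with ATR at −0.86. MHC class II genes rose in 15 of 18 and fell in 2 (median 0.78, adjusted p = 4.03e-06), HLA-DMA by 1.06. Interferon-stimulated genes rose in 31 of 46 and fell in 7 (median 0.77, adjusted p = 4.03e-06), PARP9 by 2.62, and cholesterol genes rose in 19 of 31 and fell in 2 (median 0.31, adjusted p = 0.000409). Zinc-finger genes named ZNF fell in 140 of 462 and rose in 71, or 139 and 70 adjusted over the list alone, with a median of −0.10 and a mean of 0.02 that differ in sign (lower, adjusted p = 0.0238; adjusted p = 0.234 with an estimated correlation, and 0.136 with the GC correction). In all, 5123 genes rose and 4491 fell, 53.8% of those tested, with 2349 higher and 195 lower by at least 2-fold. With the stricter filter 3388 were higher and 3301 lower.

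The comparison of the combination with the inhibitor asks what 5-azacitidine added to cells that had the inhibitor. CX3CR1, a chemokine receptor of lymphoid and myeloid cells, rose 3.34-fold from 2.14 ± 0.353 to 7.17 ± 0.311 CPM (SD, n = 3; log2 fold change 1.74 ± 0.19 SE, adjusted p = 2.37e-06). CDKN1A rose 1.88-fold (0.91 ± 0.08, adjusted p = 1.05e-07), and RGS1, which limits chemokine signalling in B cells, rose 2.59-fold (1.37 ± 0.19, adjusted p = 4.52e-05). SYNPO (adjusted p = 2.09e-05) and LINC03040, non-coding by its symbol (1.70 ± 0.19, adjusted p = 3.92e-06), also rose, and SEMA6B rose by 1.22 ± 0.21 (adjusted p = 0.000522), a call lost in DESeq2 (adjusted p = 0.101). SYNE2, which links the nucleus to the cytoskeleton, fell from 133 ± 13.2 to 90.6 ± 7.84 CPM (−0.55 ± 0.07, adjusted p = 1e-05). The centrosome and cilium genes CEP290 (−0.54 ± 0.10, adjusted p = 0.000636) and CEP162 (−0.54 ± 0.12, adjusted p = 0.00405) fell too. The fall of the circadian gene CLOCK (−0.54 ± 0.14, adjusted p = 0.0143) was lost without inhibitor replicate 3 (0.106), combination replicate 1 (0.0754), combination replicate 3 (0.105) and the pair of libraries of highest mitochondrial share (0.0935). ANKRD36B, a member of a family with shared reads and so uncertain, read −0.55 (adjusted p = 0.00478), lost without inhibitor replicate 3 (0.0619).

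UHRF1 fell by 0.23 (adjusted p = 0.00327). No change was called for HDAC3 (0.04, adjusted p = 0.703), DNMT1 (−0.06, adjusted p = 0.591), DNMT3A (0.01, adjusted p = 0.96), DNMT3B (0.23, adjusted p = 0.0896), CIITA (−0.02, adjusted p = 0.932), BCL6 (0.09, adjusted p = 0.364), MYC (−0.01, adjusted p = 0.964) or PRDM1 (−0.07, adjusted p = 0.764).

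Genes of cholesterol synthesis and uptake rose in 15 of 31 and fell in 1, or 18 and 2 adjusted over the list alone (median 0.18, adjusted p = 6.43e-10), with TM7SF2 at 0.49, MSMO1 at 0.47 and HMGCS1 at 0.46. S-phase genes fell in 12 of 48 and rose in none, or 21 adjusted over the list alone (median −0.13, adjusted p = 2.86e-13), with the replicative polymerase subunit POLA1 at −0.36 and HELLS, a chromatin remodeller of DNA methylation, at −0.33. DNA damage response genes fell in 5 of 30, or 11 adjusted over the list alone (median −0.10, adjusted p = 3.67e-05), with BRCA2 at −0.36 and FANCD2 at −0.25. Interferon-stimulated genes rose in 9 of 46, or 15 adjusted over the list alone (adjusted p = 1e-06), with IFI6 at 0.62, IFI35 at 0.61 and OAS3 at 0.36. NF-kB targets rose in 6 of 26, or 7 adjusted over the list alone (adjusted p = 3.87e-05), with EBI3 at 1.06 and CD83 at 0.62. Costimulation genes rose in 5 of 24, or 7 adjusted over the list alone (adjusted p = 5.94e-05), with CD86 at 0.43. Lists of other cell types were called higher too. T and NK cell genes rose in 4 of 16 and fell in 1, or 6 and 1 adjusted over the list alone (adjusted p = 0.000503; adjusted p = 0.0779 with the stricter filter). Genes of monocytes and granulocytes rose in 4 of 13, or 5 adjusted over the list alone (adjusted p = 0.000539), and fibroblast and endothelial genes in 5 of 8 (adjusted p = 0.0012; adjusted p = 0.114 with an estimated correlation). MHC class II genes rose in 4 of 18, or 9 adjusted over the list alone (adjusted p = 1.19e-05), with HLA-DMA at 0.29. Apoptosis regulators rose in 6 of 31 and fell in none, or 9 adjusted over the list alone (median 0.12, adjusted p = 0.000571), with BMF at 0.72 and CASP10 at 0.49. ATF4 targets fell in 7 of 24 and rose in 1, or 8 and 1 adjusted over the list alone (adjusted p = 4.82e-05; adjusted p = 0.0661 with an estimated correlation), with SLC7A5 at −0.31. MYC and ribosome biogenesis genes fell in 3 of 40, or 7 adjusted over the list alone (adjusted p = 1e-06; adjusted p = 0.114 with an estimated correlation). The 56 G2 and M phase genes were not called (6 rose and 4 fell, adjusted p = 0.888).

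In all, 806 genes rose and 506 fell, 7.34% of those tested, with 106 higher and 13 lower by at least 2-fold. These counts depended on the model, on the number of libraries left in a group and on combination replicate 2, without which they rose. With the library-number block 783 fell, and with the GC and length correction 788. Without inhibitor replicates 1, 2 or 3 in turn, 443, 477 and 465 rose and 259, 273 and 225 fell. Without combination replicates 1, 2 or 3, 252, 880 and 330 fell, and 509 rose without replicate 3. Without the pair of libraries of highest mitochondrial share, 607 rose and 421 fell, and 67.9% and 69.0% of the calls were kept.

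**Figure D3:**
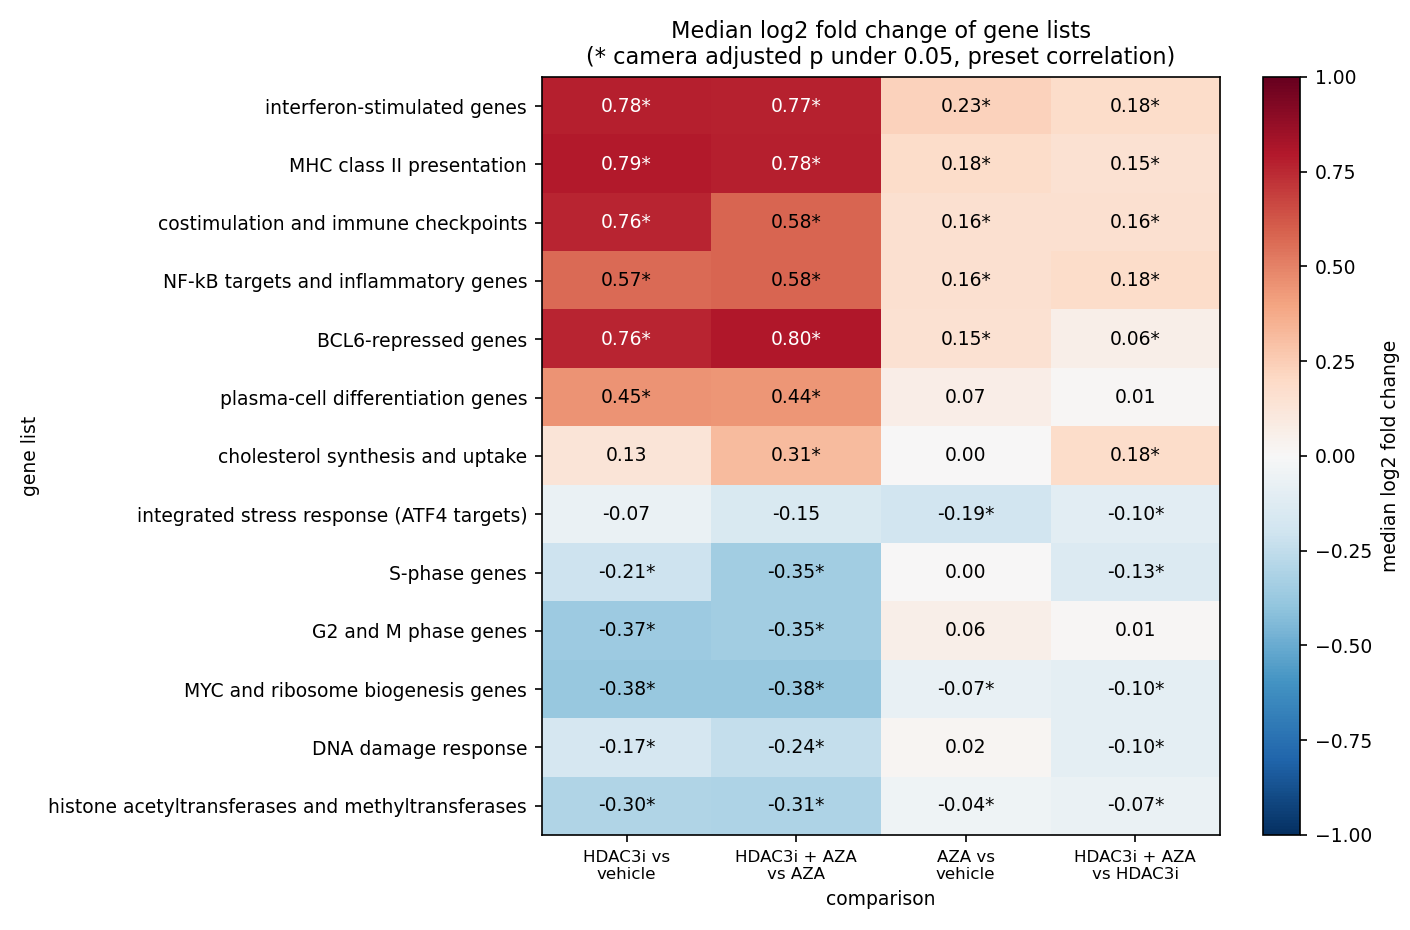
Median log2 fold change of the tested members of 13 gene lists (vertical axis) in 4 comparisons (horizontal axis), printed in each cell and shown by colour from blue (lower) to red (higher), with a star where camera gave an adjusted p under 0.05 with the preset correlation. S-phase genes had medians of −0.21 with the inhibitor, −0.35 with the inhibitor on 5-azacitidine, 0.00 with 5-azacitidine and −0.13 with 5-azacitidine on the inhibitor.

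The question of the title is about the combination, so genes were also counted that differed in the same direction from both single drugs. There were 652 genes higher in the combination than with either drug alone, CDKN1A among them, and 387 lower, UHRF1 among them. Independent lists of the same sizes would share 231.1 and 127.2 genes, and 10 simulations of groups without any drug effect gave 0. Neither value addresses joint action, since a gene that each drug alone moves in the same direction can also pass both. Log2 changes of the combination against vehicle correlated at r = 0.926 with the sum of the single-drug changes. With those of the inhibitor alone they correlated at 0.964. They lay within 0.5 of the sum for 83.9% of genes. All these changes were taken against the same vehicle libraries, so noise in vehicle alone raises both correlations. No value for groups without a drug effect was simulated for them. The share within 0.5 of the sum was not compared with the share within 0.5 of the inhibitor change alone. These values therefore cannot show whether the effects of the drugs add. The comparisons with the single drugs share the combination libraries. Higher genes numbered 366, 405 and 393 without inhibitor replicates 1, 2 and 3 and 407 without combination replicate 3. Lower genes numbered 190, 216 and 164 without the same inhibitor replicates and 174, 719 and 245 without combination replicates 1, 2 and 3. They numbered 617 with the library-number block and 608 with the GC and length correction.

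The effects of each drug with and without the other were compared across genes in 3 relations, and genes are not independent replicates. The log2 changes by the inhibitor, alone and on 5-azacitidine, correlated at r = 0.887 (jackknife SE 0.019 over libraries). Those by 5-azacitidine, alone and on the inhibitor, correlated at r = 0.269 (SE 0.059), and the average effects of the drugs at r = 0.412 (SE 0.171). The value of 0.269 fell whichever library was left out, to between 0.175 (without 5-azacitidine replicate 1) and 0.235. Each of these fits filtered the genes anew with 2 libraries in a group, so the genes changed with the libraries. The fall cannot be laid to single libraries, and the SE also holds that change of genes. Without a filter on low counts these values were 0.383, 0.025 and 0.123, and with the stricter filter the first pair were 0.953 and 0.502. Of 770 genes that 5-azacitidine raised alone, 315 also rose on the inhibitor, where independent lists would share 34.73, and of 849 it lowered, 159 also fell (24.04). Genes with the same sign on the inhibitor made up 87.27% of the raised and 87.28% of the lowered genes.

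The interaction asks whether the 5-azacitidine effect differed with the inhibitor present. It was called for 128 genes, 47 with a more positive effect in the combination and 81 with a more negative one, 0.72% of those tested. FGR rose with either drug, to 67.8 ± 4.15 CPM with the inhibitor and 84.3 ± 1.99 CPM with both, less than the sum of its log2 changes (interaction −1.37 ± 0.13 SE, n = 3, adjusted p = 2.1e-06). FCER2 (−0.63, adjusted p = 0.00077), PARP9 (−0.93, adjusted p = 0.017) and XBP1 (−0.34, adjusted p = 0.024) also had less in the combination than the sum of their log2 changes. For CDKN1A the interaction was not called (−0.66 ± 0.19, adjusted p = 0.0956), but it passed with no filter on low counts (adjusted p = 0.0378), in DESeq2 (0.0204) and without 5-azacitidine replicate 1 (0.0416). No interaction was called for HDAC3 (0.09, adjusted p = 0.665), DNMT1 (0.10, adjusted p = 0.618), DNMT3A (−0.04, adjusted p = 0.936), DNMT3B (0.18, adjusted p = 0.57), UHRF1 (0.07, adjusted p = 0.716), CIITA (0.13, adjusted p = 0.616), BCL6 (0.20, adjusted p = 0.218), MYC (0.23, adjusted p = 0.187) or PRDM1 (−0.14, adjusted p = 0.805). Leaving out any library but vehicle replicate 2 moved at least 1 of these counts by more than 1.5 times, over ranges of 10 to 188 and of 20 to 501. They also depended on the method, with 106 positive and 282 negative in DESeq2, 73 and 241 with no filter on low counts, 24 positive with library totals only, 28 positive without the pair of libraries of highest mitochondrial share, and 135, 166 and 123 negative with the stricter filter, the library-number block and DESeq2 size factors.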

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

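Of the tests in this part, the correction for GC content and length, the fit without the 2 libraries of highest mitochondrial share and the GC slope without single libraries were chosen only after the result was seen. A test of the difference itself, the interaction, drew attention to every result here: the effect of 5-azacitidine differed between cells with and without the inhibitor for 47 genes in the positive and 81 in the negative direction.

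FGR, at −1.37 on the log2 scale, had the lowest adjusted p of the genes named here (2.1e-06), with 2.57, 67.8, 8.28 and 84.3 CPM in vehicle, inhibitor, 5-azacitidine and combination. CUEDC1 was at −1.45, with 0.600, 17.2, 2.56 and 26.7 CPM in the same order. KLHL14, a B-cell gene, was at −1.4, with 0.720, 8.96, 1.86 and 8.76 CPM. These 3 calls held in each of the 23 alternative fits in which the genes were tested. PARP15 was at −1.45 (adjusted p = 0.023), a call lost in limma voom (0.0583) and without vehicle replicate 1 (0.0956) or 3 (0.0773), inhibitor replicate 2 (0.0606) or 3 (0.0595), 5-azacitidine replicate 2 (0.0557) or 3 (0.0974), or combination replicate 1 (0.0717). The neuronal membrane glycoprotein gene GPM6A was at 1.21, with 2.50, 14.1, 0.874 and 11.5 CPM, a call lost without 5-azacitidine replicate 2 (adjusted p = 0.0649). GGT7 at 0.98 (adjusted p = 0.047), AAK1 at 0.75 (0.0448) and ABAT at 0.71 (0.0446) passed narrowly. GGT7 and AAK1 were lost without any single library other than combination replicate 2 (adjusted p from 0.0648 to 0.133 and from 0.067 to 0.175), and ABAT without any other than vehicle replicate 3, 5-azacitidine replicate 1 and combination replicate 2 (0.092 to 0.119).

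Genes of cholesterol synthesis and uptake had an adjusted p of 9.7e-08 for the difference, higher, with a median of 0.18 and 2 genes called of 31, or 9 adjusted over the list alone, and kept the call with an estimated correlation (adjusted p = 0.00652). S-phase genes had 2.91e-09, lower, with a median of −0.10 and 3 called of 48, or 4 adjusted over the list alone (adjusted p = 0.163 with an estimated correlation). DNA damage response genes had 0.00229, lower, with a median of −0.09 and 1 called of 30, or 5 lower and 2 higher adjusted over the list alone (adjusted p = 0.168 with an estimated correlation). Glycolysis and hypoxia genes had 0.00116, higher, with a median of 0.11 and none called of 27, or 1 adjusted over the list alone (adjusted p = 0.59 with an estimated correlation). BCL6-repressed genes had 0.0302, lower, with a median of −0.13 and 1 called of 26, FCER2, or 4 adjusted over the list alone (adjusted p = 0.163 with an estimated correlation). That call was lost without vehicle replicate 3 (0.0952), inhibitor replicate 1 (0.0551), 5-azacitidine replicate 3 (0.066) or combination replicate 2 (0.0739). Histone deacetylases and HDAC3 co-repressors had 0.0484, higher, with a median of 0.08 and 1 called of 20, or 2 adjusted over the list alone (adjusted p = 0.168 with an estimated correlation). Zinc-finger genes named ZNF had 0.0484, lower, with a median of −0.05 and 3 called of 462 (adjusted p = 0.668 with an estimated correlation). The call of the deacetylases was lost without any single library other than inhibitor replicate 3 and combination replicate 1 (0.0503 to 0.0896) and without the 2 libraries of highest mitochondrial share (0.0699). That of the ZNF genes was lost without vehicle replicate 3, inhibitor replicate 1 or 3, 5-azacitidine replicate 2 or 3, or combination replicate 1 or 3 (0.0551 to 0.256), and without those 2 libraries (0.0616).

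The interaction rose with the GC content of the genes, with a slope of 0.0926 log2 units per 10% GC over 9754 genes, which fell to 0.061 without combination replicate 1, the library of steepest slope (0.126). As the whole cause of the calls this trend was argued against, because 57.8% of the called genes stayed called in the same direction after the correction, FGR at −1.44 and CUEDC1 at −1.56 among them, and because the lists of cholesterol (3.19e-08) and S-phase genes (5.78e-12) kept their calls. It may account for others, since glycolysis (0.0655) and ZNF genes (0.282) lost theirs. A GC-dependent recovery that differs between single libraries stays open: 10 of 200 splits of the libraries within the inhibitor arms gave as large a slope, a share of 0.05, and the highest other slope was 0.102. A response of these cells to both drugs together, which the design names, also stays open and was not tested apart from it.

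Chance was not excluded for the number of interaction calls, and the splits tried could not test it. Of 100 splits, drawn from 200 that keep each library in its inhibitor arm, 8 called as many genes as the real 128, the real split included. The highest other value was 2527, in the split that swaps 5-azacitidine and its absence in 1 arm, which turns the interaction into the sum of the 5-azacitidine effects. So large a value points to a structure of the samples, the shared effect of 5-azacitidine. Without that split 7 gave as many, the real one included, the highest other being 483. Splits that keep the groups of 1 arm and mix those of the other also carry the 5-azacitidine effect. The remaining splits are therefore not a chance level for the interaction. The counts also moved with single libraries. The positive count was 14 and 12 without vehicle replicates 1 and 3, 11, 12 and 13 without inhibitor replicates 1 to 3, 10 and 18 without 5-azacitidine replicates 2 and 3, and 15, 188 and 20 without combination replicates 1 to 3. In the same order the negative count was 34 and 28, 35, 27 and 24, 25 and 35, and 20, 501 and 51, and it was 141 without 5-azacitidine replicate 1.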

How the results depend on the processing

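Chosen only after the data were seen were the correction for GC content and length, leaving out the 2 libraries of highest mitochondrial share, and leaving out mitochondrial genes. No called gene or list changed direction in the alternatives run, except DNMT1 in the combination against 5-azacitidine. Gene results not tested under the stricter filter have no value there. With the replicate number as a block, 537 gene results kept direction and side of the threshold and 6 lost their call, and 119 list results kept it and 3 lost it. Neither number clearly paired the samples: residual correlations between groups ran from −0.059 to 0.066 for libraries of the same replicate number and from −0.065 to 0.061 for others. For the number in the library names they ran from −0.034 to 0.066 (median 0.015) and from −0.065 to 0.061 (median −0.001). By the same measure limma voom left 537 gene results in place, DESeq2 535, the GC correction 516 and the fit without the 2 libraries 523. All 29 counts and correlations stayed within the limits set with the replicate block and without mitochondrial genes, as did the 17 that were run in limma voom. For every change of value listed here the cause was not tested, unless the setting itself tests fewer genes or samples. Depth limited a gene with no counts in a library to 0.0826 to 0.0835 CPM. For the interaction edgeR recovered 46% of simulated 1.5-fold changes and 70% of 2-fold changes.

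The stricter filter, which tests fewer genes, gave 3019 higher genes for the inhibitor against vehicle, 3378 for the combination against vehicle, 3388 against 5-azacitidine and 135 in the negative direction of the interaction. The lower counts of these comparisons of 2 groups were 3117, 3564 and 3301. Asking also for a 2-fold change left 2240 higher and 155 lower for the inhibitor, 152 and 13 for 5-azacitidine, 2658 and 228 for the combination, 2349 and 195 for the combination against 5-azacitidine, 106 and 13 against the inhibitor, and 2 and 8 for the interaction. The library-number block gave 783 lower for the combination against the inhibitor, 617 lower than both single drugs and 166 in the negative direction of the interaction. The GC correction gave 788 and 608 for the first pair of these. The interaction had 24 positive calls with library totals only, 28 without the 2 libraries, 73 positive and 241 negative with no filter, 106 and 282 in DESeq2, and 123 negative with DESeq2 size factors. The correlations across genes, for 5-azacitidine, the inhibitor and the average effects, were 0.025, 0.383 and 0.123 with no filter. The first pair were 0.502 and 0.953 with the stricter filter and 0.176 and 0.854 without the 2 libraries. An estimated correlation left 9 lists higher and 3 lower for the inhibitor, 2 and 0 for 5-azacitidine, 11 and 4 for the combination, 5 lower for the combination against 5-azacitidine, 3 lower against the inhibitor, and 1 and 0 for the interaction. In fry 11 lists were higher for 5-azacitidine.

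Leaving out each library in turn gave 497 to 948 higher and 508 to 1032 lower for 5-azacitidine, lowest without vehicle replicate 1 and 5-azacitidine replicate 2, with 520 lower without vehicle replicate 1 and 538 without vehicle replicate 3. For the combination against the inhibitor the ranges were 443 to 968 and 225 to 880, for genes beyond both drugs 366 to 741 and 164 to 719, and for the interaction 10 to 188 and 20 to 501. Lists lower in the interaction were 2 to 5, with 2 without vehicle replicate 3, inhibitor replicate 1 or 5-azacitidine replicate 3. For the combination against the inhibitor, leaving out inhibitor replicates 1 to 3 gave 443, 477 and 465 higher and 259, 273 and 225 lower. Combination replicates 1 to 3 gave 252, 880 and 330 lower, and replicate 3 gave 509 higher. Beyond both drugs the inhibitor replicates gave 366, 405 and 393 higher and 190, 216 and 164 lower, the combination replicates 174, 719 and 245 lower, and combination replicate 3 gave 407 higher. The libraries that moved the interaction counts are given with them in the first part. The correlation was 0.175 to 0.235 for 5-azacitidine, lowest without 5-azacitidine replicate 1, and 0.853 to 0.869 for the inhibitor. These fits also filtered the genes anew, so the genes differ from those of the main fit.

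Results that changed sign were otherwise not called. With the GC correction these were DNMT1 (−0.036) and HDAC3 (−0.046) for the inhibitor, HDAC3 (−0.07) for the combination, BCL6 (−0.098), DNMT1 (−0.005) and HDAC3 (−0.032) for the combination against 5-azacitidine, CIITA (0.007) and HDAC3 (−0.024) against the inhibitor, and UHRF1 (−0.009) in the interaction. With the library-number block they were CIITA (0.064) and MYC (0.011) for the combination against the inhibitor and DNMT1 (0.006) for the combination, which was 0.054 with the stricter filter. DNMT3A for the combination against the inhibitor was −0.004 in the fit of only the 2 groups and −0.031 without the 2 libraries. Without single libraries the ranges were −0.04 to 0.13 for DNMT3A and −0.004 to 0.102 for DNMT3B under 5-azacitidine, −0.015 to 0.081 for BCL6 in the combination against 5-azacitidine, −0.089 to 0.076 for CIITA, −0.029 to 0.092 for DNMT3A and −0.062 to 0.055 for MYC against the inhibitor, −0.07 to 0.016 for DNMT1 in the combination, and −0.12 to 0.054 for DNMT3A in the interaction.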

Other observations

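Of the tests in this part, the comparison of long genes with matched genes and the use of CD2 and of the ratio of CD3D to CD3E were chosen only after the result was seen, as were the starting levels in the next paragraph.

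Genes with large changes under the inhibitor were often nearly silent in vehicle. Of the 4712 genes it raised, 2240 rose at least 2-fold, and 1687 of these (75.3%) were under 1 CPM in vehicle, against 29.9% of all tested genes. The share was 60.6% for the genes it lowered at least 2-fold, so it was not particular to rises. Of the genes raised at least 2-fold by 5-azacitidine 133 of 152 (87.5%) were under 1 CPM in vehicle, and by the combination 1928 of 2658 (72.5%). Of the genes that the inhibitor lowered at least 2-fold and whose biotype was known, 37.5% were long non-coding RNAs, against 16.8% of the tested genes. Of 17 heat shock and proteotoxic stress genes 11 fell and 3 rose under the inhibitor (adjusted p = 0.00232; adjusted p = 0.268 with an estimated correlation), with the chaperones HSPH1 (−0.79) and HSP90AA1 (−0.71) lower and HMOX1, which degrades haem, at 3.75. S100A4 and LGALS1, which many motile cells express, rose by 3.93 and 2.46, in a list of cytoskeleton and adhesion genes of which 22 rose and 5 fell of 32, or 23 and 5 adjusted over the list alone (adjusted p = 1.6e-05; adjusted p = 0.014 with an estimated correlation).

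Lists of other tissues were also called higher under the inhibitor. Fibroblast and endothelial genes rose in 6 of 8 (adjusted p = 0.0159; adjusted p = 0.21 with an estimated correlation) and neuronal genes in 6 of 9 (0.0176; 0.0765 with an estimated correlation). Epithelial genes rose in 3 of 5 (0.0454; 0.154 with an estimated correlation), a call lost without vehicle replicate 2 (0.0689) or inhibitor replicate 1 (0.0631) and with the GC correction (0.056). None fell in these lists, but only 8 of 21, 9 of 28 and 5 of 18 members were tested. The filter on low counts used all groups, so members silent in vehicle were tested mainly where a drug raised them. Of 118 tested genes at 0 in vehicle, the inhibitor raised 117 at least 2-fold. The direction in these lists was therefore partly fixed by the filter.

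Genes that span a long stretch of the genome were over-represented among those 5-azacitidine lowered, though most were not called: of genes of at least 5 CPM over 200 kb, 174 were lower, 20 higher and 388 not called. The long ones were 21.5% of the 808 genes it lowered, against 4.5% of those not called and 3.7% of those raised, and on the inhibitor the shares were 21.7%, 5.2% and 2.9%. A bias by GC content or exonic length was argued against: 578 long genes were lower than 3 genes each matched on GC, exonic length and expression by −0.13 (95% bootstrap interval −0.149 to −0.11), and by −0.078 on the inhibitor (−0.093 to −0.063), while the inhibitor alone moved them the other way (0.096, 0.056 to 0.136) and the interaction was 0.052 (0.036 to 0.068). These intervals resample genes, which are not independent replicates, and hold no spread between libraries. Over the fits that left out each library, the difference was −0.137 to −0.125 for 5-azacitidine alone. On the inhibitor it was −0.086 to −0.066. Nor was the fall of long genes the work of 5-azacitidine replicate 1, without which the difference was −0.137 (−0.157 to −0.117). A hypothesis is that 5-azacitidine may hinder transcription over long distances, which no test here could separate from other properties of long genes.

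Genes of other blood lineages rose under the inhibitor, beside those of other tissues, ITGAM to between 11.4 and 16.3 CPM and CD3E to between 6.12 and 9.75 CPM in the 6 libraries with it. Monocytes or granulocytes in the cultures were argued against, since LYZ, S100A8 and S100A9, which fill such cells, reached at most 2.42 CPM in those libraries. Against T cells stand CD3D, whose highest level was 0.0753 of the lowest CD3E level, and CD2, at most 0.0562 CPM, since T cells would bring these with CD3E. Other markers moved as added T cells would move them: TRAC rose from 88.7 CPM in vehicle to 240 with the inhibitor and 237 with both drugs, CD3G from 0.0927 to 0.874 and 2.94, and CD4 from 0.0182 to 0.349 and 0.583, and CD3E and TRAC failed the test first set, that CD3D, CD3E, CD3G and TRAC stay at or under 5 CPM. T cells as the source of all these genes were thus argued against by CD3D and CD2 alone, and the other hypothesis, found and tested on the same data, is that the lymphoma cells themselves may express them.

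In each comparison of 2 groups the 6 libraries make 10 splits, too few for a share under 0.05, and 1 of 10, the real one, gave as many genes as found. The real counts were 9166 for the inhibitor against vehicle, 1619 for 5-azacitidine, 10207 for the combination, 9614 for the combination against 5-azacitidine and 1312 against the inhibitor, and in edgeR the highest other count was 0 in each. Every other split mixes libraries of both groups, which widens the spread within each, so that 0 is not a chance level.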
